A study of Mus musculus with 23 samples.

How the data were processed

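RNA was sequenced from dorsal root ganglion neurons of E13 mouse embryos, wild type or mutant for a gene trap in Tmem184b, per the labels. Cells were taken at day 0 or after 14 days of culture with NGF and the antimitotic drug FDU, and some mutant cultures received a lentivirus carrying TMEM184b and the fluorescent marker VENUS. The 23 samples fell into 5 groups: 4 wild-type and 5 mutant samples at day 0, 4 wild-type and 5 mutant samples at day 14, and 5 mutant samples with the virus at day 14. No label names a control virus, so an effect of the virus itself was not separated from an effect of the restored gene. No label gives a sequencing batch or date.

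The deposited table holds 1 normalised count per gene and sample, a signal that the authors made from Salmon 0.11.1 estimates on mm10 with DESeq2, per the submitters' processing notes. It has 25025 genes and transcripts, of which 3879 were at 0 in all samples. A symbol had been turned into a date in 26 cases, and these could not be assigned to a gene. In GENCODE M21, 24373 of the symbols were found, and 15733 of the symbols tested, which gave positions, lengths and GC content.

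The sum of the normalised counts ran from 21.5 to 28.1 M (M for mega) per sample. Whole reads were looked for in the steps between low values: between 85.5% and 92.7% of the low values of a sample came out whole at a tolerance of 0.1 read, which was too few to recover the reads. The steps put the depth at about 19.2 to 31.5 M reads per sample, and no count model was run.

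Values were tested as log2(normalised count + 1) with limma 3.58.1 in R 4.3.3, with 5 group means in 1 fit of all 23 samples and a trend of the variance on the mean. A gene was tested if it reached a value of at least 10 in at least 4 samples, which left 15992 genes. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over the genes tested in each of 7 contrasts. A gene was called at an adjusted p under 0.05. All fold changes are on the log2(normalised count + 1) scale, which understates the change of genes with low values, and are given ± the standard error. Means are given ± SD over the 4 wild-type or 5 mutant samples. The p-values measure the spread between these samples, since each group holds few embryos.

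Before the data were examined, the groups, contrasts, tests, alternatives, 29 gene lists and the rule for naming genes were fixed. Of the lists, 26 were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the 26 lists of a contrast, and again with an estimated correlation. The other 3 were checks: sex-linked genes, the Tmem184 family and neighbours of Tmem184b. The number of members called was counted over all genes tested and adjusted over the list alone. The rule names Tmem184b, the 10 genes that rose and the 10 that fell most in each contrast among called genes with a mean of at least 50 in 1 of the groups, the 4 members with the smallest p of each list described, and any member of the list of itch neuron genes and of the 3 check lists. Predicted genes and pseudogenes were not named.

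Tmem184b was also compared between groups with exact two-sided permutation tests on the normalised counts. The count of genotype genes moved back by the virus was set beside the number expected of independent lists, and the correlation of the fold changes beside 50 simulations of unchanged groups, because both contrasts use the unrescued mutants.

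The series' design text says that the day 0, day 14 and virus samples of a mutant came from the same mouse, and the titles share letters. One day 0 mutant carries no letter in its title, while its column in the deposited table carries the letter E, and it was placed either in its own block or with animal E. After the group means were removed, partner samples had correlations of 0.0539 to 0.225 between mutants at day 0 and day 14, 0.0218 to 0.291 between day 14 without and with virus, and 0.126 to 0.162 between wild-type samples with the same number. The median over samples that were not partners was between -0.0552 and -0.0197. Their highest values were 0.149 between mutants at day 0 and day 14 and 0.143 between day 14 without and with virus, above some partners. In wild type the highest was 0.0626, below all partners. The animal was therefore used as a block in alternative fits.

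The test was checked on simulated data with 200 genes changed by known amounts. For the mutant against wild type at day 0, 78% of genes changed 2-fold and 98% of genes changed 4-fold were recovered among 15369 genes, and 1.82% of the calls were false. For the same contrast at day 14, these shares were 88% and 100% among 14111 genes, with 6.45% false. For virus against no virus they were 82% and 98% among 14178 genes, with 5.52% false.

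Alternatives changed the pseudocount, the filter on low values, the scaling (median of ratios or quantile normalisation), the samples in the fit, the variance trend, sample weights and the block, added covariates, and left out each sample in turn. Alternatives added after the data were seen removed a trend with transcript length or GC content, left out genes lost in wild-type culture, left out the 3 day 0 mutants that stand apart or animal H, and split the animals between the contrasts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No sample was left out of the reported values.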

Results

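The data are normalised RNA-seq counts of 25025 genes and transcripts in 23 samples of dorsal root ganglion neurons, the sensory neurons of the body, from E13 mouse embryos. Wild-type neurons were sampled at day 0 (n = 4) and at day 14 of culture (n = 4), and neurons with a gene trap in Tmem184b at day 0 (n = 5) and day 14 (n = 5). Mutant neurons that had received a lentivirus with TMEM184b were sampled at day 14 (n = 5). The sums of normalised counts were 21.5 to 22.8 M per sample at day 0 and 22.5 to 28.1 M at day 14. The log2 values of replicates had correlations across genes, which are not independent replicates, of 0.972 to 0.988. The first principal component held 73.3% of the variance and parted the days in culture, and the second held 12.2% and parted the cultures with virus from those without.

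Tmem184b, which codes for a transmembrane protein, lies on chromosome 15 from 79360684 to 79403569 on the minus strand (mm10). At day 0 it had 1093 ± 135 normalised counts in wild type (SD, n = 4) and 23.3 ± 9.09 in mutant (SD, n = 5), or 2.13% of wild type (exact two-sided permutation p = 0.00794). At day 14 it had 1458 ± 200 in wild type and 50.7 ± 8.71 in mutant, or 3.48% (exact p = 0.00794). With the virus it had 127 ± 27.5, which was 2.50 times the mutant value (exact p = 0.00794) and 8.72% of wild type. The p-value against the mutant treats the samples as independent, although those with and without virus came in pairs from 5 animals. An exact test that keeps 5 pairs cannot go under 0.05. The deposited counts were made on the mouse transcriptome, and the sequence of the TMEM184b in the virus is not in the labels. If that sequence differs from the mouse gene, the counts understate its level. The related gene Tmem184c had 1155 ± 61.6 counts in wild type and 1233 ± 166 in mutant at day 0, a log2 fold change of 0.08 (limma adjusted p = 0.63).

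**Figure D1:**
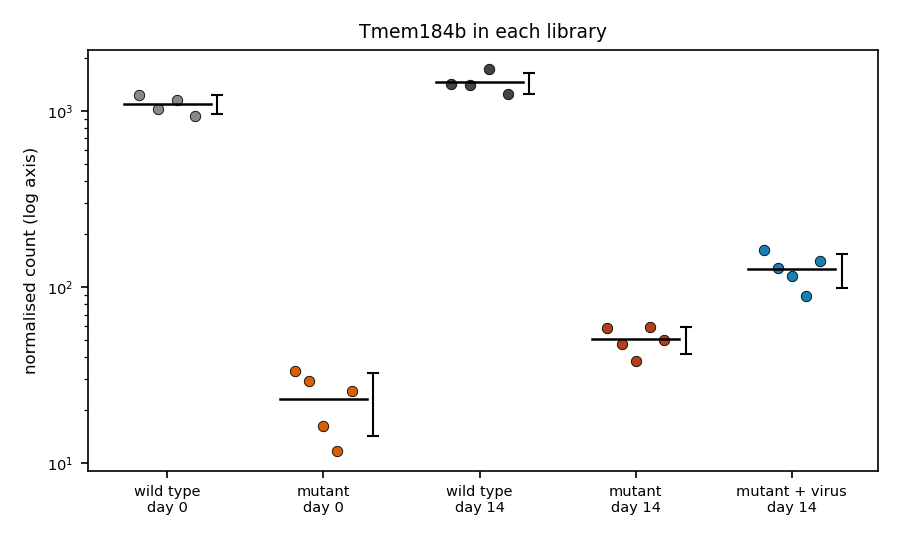
Tmem184b in each sample as a normalised count on a log axis, with 1 point per sample, the group mean as a bar and the SD as an error bar. All 5 mutant samples without virus lie between 11.7 and 33.5 at day 0 and between 38.1 and 59.4 at day 14, and the 5 with virus between 89.2 and 163.

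The first comparison asks how mutant and wild-type samples differed when freshly taken. At day 0, 13 of 32 genes induced by MAP kinase signalling, 17 of 42 synaptic and 20 of 66 ion channel genes were called higher in mutant, and 14 of 28 neurogenesis genes lower. With an estimated correlation the neurogenesis list still passed (adjusted p = 0.00937) and the others did not (adjusted p = 0.165, 0.165 and 0.362). Insm1, a transcription factor of newly born neurons, fell from 1351 ± 243 counts in wild type to 438 ± 158 in mutant, a log2 fold change of -1.68 ± 0.22. Fosb, an immediate early transcription factor, rose from 10618 ± 4674 to 42712 ± 8750, or 2.07 ± 0.31. The itch receptor Mrgprx1 rose from 3.38 ± 1.09 to 76.2 ± 44.3, or 3.95 ± 0.43, and the sodium channel Scn11a from 96.8 ± 15.2 to 552 ± 278, or 2.35 ± 0.38.

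Of 15992 genes, 1870 were called at day 0, with 1146 higher and 724 lower in mutant. A change of at least 2-fold was seen in 328 and 167 of them. Quantile normalisation turned the majority, with 1324 higher and 1513 lower of 2837 called, and sample weights gave 6328 genes. The genes that rose most, beside Mrgprx1, were Iqcm, with a log2 fold change of 5.02 ± 0.43, and Raet1e, Nfatc2, Csrnp1, Tnxb, Ptgds and Fosl2, with values from 2.58 to 3.56. Csrnp1, an immediate early gene, went from 430 ± 424 to 2110 ± 613 counts. Nr4a3 and Acan also ranked among the first 10, but 4 and 6 of the samples, left out in turn, each ended their calls. The genes that fell most, beside Tmem184b, were Eno1b (-5.44), Zfp429 (-4.65), Robo3 (-3.91), Lhx1 (-3.90), Pax2 (-3.40), Irx1 (-3.39), Lbx1 (-3.36), Neurod4 (-3.30) and Skor1 (-3.21). The calls of Pax2, Lbx1 and Skor1 each ended without any of 6 samples, that of Robo3 without any of wild types 2 to 4, and that of Raet1e without wild type 1. Eno1b is near-identical to Eno1 and Zfp429 belongs to a family of similar genes, so their counts are uncertain. Neurod4, a transcription factor of neural precursors, went from 255 ± 99.7 to 29.0 ± 17.6 (limma adjusted p = 0.000797).

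Of 28 measured neurogenesis genes, 14 fell and none rose, and 18 fell when adjusted over the list alone (camera adjusted p = 5.12e-11, and adjusted p = 0.00937 with an estimated correlation). Besides Insm1, the members with the smallest p were Neurog1 (-2.81 ± 0.45), Neurog2 (-2.16 ± 0.36) and Six1 (-0.87 ± 0.15), which are transcription factors of sensory neuron birth. Of 30 proliferation genes, 8 fell, and 10 when adjusted over the list alone, among them the replication gene Mcm7 (-0.67), its partner Mcm2 (-0.57), the mitotic kinase Aurka (-0.85) and the cell cycle factor E2f1 (-0.61). The list had camera adjusted p = 9.76e-08, and adjusted p = 0.165 with an estimated correlation.

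Of 32 genes induced by MAP kinase signalling, 13 rose, and 20 when adjusted over the list alone (camera adjusted p = 2.06e-09, and adjusted p = 0.165 with an estimated correlation). Nr4a1 went from 3096 ± 1291 to 9646 ± 2318 counts, Nr4a2 rose by 1.55 and Jund by 0.77. The mean log2 value of this list was 9.51 to 9.75 in wild types 1 to 3, 10.7 in wild type 4, 10.2 in mutant H and 10.9 to 11.1 in the other 4 mutants. Of 42 synaptic vesicle genes, 17 rose, and 20 when adjusted over the list alone (camera adjusted p = 2.75e-10, and adjusted p = 0.165 with an estimated correlation), including Syngr1 (0.46), Syt5 (0.59), Vamp1 (0.77) and Syngr3 (0.46). Of 66 ion channel genes, 20 rose, and 27 rose and 1 fell when adjusted over the list alone (camera adjusted p = 5.87e-10, and adjusted p = 0.362 with an estimated correlation). Piezo2, the touch channel, went from 3515 ± 916 to 7692 ± 2657 counts, and the potassium channel genes Kcna2 and Kcnab2 rose by 0.79 and 0.43. Genes with long transcripts tended to be higher in mutant at day 0, with a median log2 fold change of -0.04 in the tenth with the shortest and 0.14 in the tenth with the longest, and the ion channel median of 0.43 was 0.36 with the length trend removed.

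Of 20 itch neuron genes, 4 rose, and 5 when adjusted over the list alone (camera adjusted p = 0.0171, and adjusted p = 0.719 with an estimated correlation). These were Mrgprx1, Crlf2 (0.80), Il4ra (0.53) and Il31ra, which stayed under 10 counts in both group means and whose call ended when any of 6 samples was left out. Some members not called over all genes still had ranges that did not overlap. Trpv1 had 2207 to 2447 counts in mutant and 924 to 1149 in wild type, and Il13ra1 92.8 to 173 and 70.7 to 89.9. Lpar3 was lower in mutant, at 33.3 to 59.0 against 82.2 to 105. Of 16 genes of nonpeptidergic nociceptors, 5 rose, and 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0128, and adjusted p = 0.693 with an estimated correlation). Among them were Cd55 (1.14) and Grik1 (1.18). Of 40 cytoskeleton genes, 7 rose, and 10 when adjusted over the list alone, with Prph, a neurofilament of small sensory neurons, at 0.65 (camera adjusted p = 0.000792, and adjusted p = 0.693 with an estimated correlation). Of 43 interferon genes, 6 rose, with the same number adjusted over the list alone (camera adjusted p = 0.01, and adjusted p = 0.719 with an estimated correlation). No ribosomal protein gene of 67 was called by limma over all genes or adjusted over the list alone, while the list had a median of -0.16 (camera adjusted p = 0.000128, and adjusted p = 0.749 with an estimated correlation).

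Some markers of other cells and of tissue differed between these samples too. Of 26 glial genes, 4 rose, among them S100b (1.83) and Mal (1.74), with camera adjusted p = 0.0791, and no member was called by limma among 23 fibroblast genes (camera adjusted p = 0.102) or 15 endothelial genes (camera adjusted p = 0.462). The glial gene Sox10 had 5463 counts in mutant H and 1427 to 1699 in the other mutants. In wild type it had 2146 in wild type 4 and 4854 to 5823 in wild types 1 to 3. Of 24 measured spinal cord genes, a list made after the day 0 genes were seen, 8 fell, and 12 when adjusted over the list alone, and their mean log2 value was 6.20 to 7.22 in wild types 2 to 4, 3.42 in wild type 1 and 3.48 to 4.21 in the mutants. Lhx1, Pax2, Lbx1, Skor1 and Robo3 are genes of spinal cord neurons. Their counts in wild type 1 were 9.65, 3.23, 3.22, 3.22 and 1.07, within or below the range of the mutants. The falls of these genes in mutant therefore rest on wild types 2 to 4. The ratio of adult to embryonic beta globin (Hbb-bs and Hbb-bt over Hbb-y and Hbb-bh1, chosen after their values were seen), which rises as blood formation moves to the fetal liver, had a log2 value of -0.17 ± 0.28 in wild type (SD, n = 4) and 1.55 ± 0.36 in mutant (SD, n = 5; exact two-sided permutation p = 0.00794).

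The day 0 count depended on single samples: it was 924 without the unlettered mutant, 1016 without FG, 1229 without C, 3034 without H, 1162 without wild type 1 and 1226 without wild type 2. Without the unlettered mutant, FG and C together, which stand apart on the fourth principal component (1.99% of the variance), 60 genes were called, a setting chosen after seeing the data that leaves 2 mutants, where other pairs of 2 mutants gave 144 to 2350. Of 95 genes that the naming rule covers and that were called at day 0, 9 held their calls then (Tmem184b, Insm1, Mrgprx1, Iqcm, Csrnp1, Irx1, Zfp429, S100b and Syngr1). The calls of the other 86 ended, and these include all other genes given above as called, risen or fallen at day 0. Their fold changes kept their direction, as in Fosb (1.75), Neurog1 (-2.06), Scn11a (1.49), Lhx1 (-3.11) and Neurod4 (-2.39), with larger standard errors (0.43 for Fosb, against 0.31).

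The second comparison asks how mutant and wild type differed after 14 days of culture. These cultures came from the animals of day 0, so the stage of the embryos and other differences between the animals were not separated from the genotype. In mutant, 15 of 20 itch neuron and 10 of 17 peptidergic nociceptor genes were called higher at day 14 and 21 of 40 cytoskeleton genes lower, and no list passed with an estimated correlation (adjusted p = 0.264, 0.264 and 0.315 for these). Trpa1, the channel for irritants, had 8.16 ± 5.76 counts in wild type and 1199 ± 840 in mutant, a log2 fold change of 6.81 ± 0.90. Trpv1, the capsaicin and heat channel, rose from 802 ± 463 to 4687 ± 1501, or 2.69 ± 0.39, and Tac1, the gene of substance P, from 3878 ± 2133 to 28948 ± 6949, or 3.08 ± 0.33. Map1b, a microtubule protein of axons, fell from 108374 ± 9490 to 52147 ± 11106, or -1.08 ± 0.17.

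At day 14, 4224 genes were called, with 2003 higher and 2221 lower in mutant, of which 614 and 450 changed at least 2-fold. Quantile normalisation turned the majority, with 1716 higher and 1568 lower. After Trpa1, the genes that rose most were Cyp2j12, Cysltr2, Fgg, A3galt2, Gfra2, Tspan8, Pde4c, Cdh1 and Gfra3, with log2 fold changes from 4.90 to 6.04. Gfra2 and Gfra3 are receptors for growth factors of the GDNF family and went from 7.49 ± 9.35 to 226 ± 132 and from 54.5 ± 39.4 to 1439 ± 765 counts. The genes that fell most, beside Tmem184b, were Eno1b (-5.73), H2-T24 (-4.56), Entpd4 (-4.11), Fgf21 (-3.78), Cd276 (-3.60), Kif21b (-3.23), Cdsn (-3.17), Acacb (-2.84) and Lama1 (-2.80). Cd276, a surface protein of the B7 family, went from 596 ± 68.7 to 49.6 ± 15.4. The counts of Eno1b, H2-T24 and Entpd4 are uncertain because each has close copies, and the call of Entpd4 ended without any of 6 samples.

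Of 20 itch neuron genes, 15 rose and none fell, and 16 rose when adjusted over the list alone (camera adjusted p = 3.72e-10, and adjusted p = 0.264 with an estimated correlation). Beside Trpa1 and Trpv1 these included the receptor gene Osmr (4.21), the leukotriene receptor gene Cysltr2 (5.74), the itch receptor genes Mrgpra3 (3.03) and Mrgprx1 (1.55), Il31ra (1.54), the kinase gene Jak1 (1.81), S1pr1 (2.70) and Plcb3 (0.83). Nppb, a peptide of itch neurons, was listed at 0 in wild type and in mutant H and had 14.0 to 23.1 counts in the other 4 mutants. Mutant H stood nearer to wild type, with a mean log2 value of the list of 6.10, against 7.19 to 7.80 in the other mutants and 4.47 to 5.66 in wild type. Its counts of Mrgpra3 (23.9), Mrgprx1 (1581) and Il31ra (21.7) were within or below the range of wild type, and its Cysltr2 count was 2.07. Hrh1, Sst, Lpar5, Crlf2 and Npr3 were not called. Of 17 peptidergic nociceptor genes, 10 rose and 3 fell, and 11 rose when adjusted over the list alone, including Adcyap1 (3.27) and Gal (2.71), with camera adjusted p = 6.4e-05, and adjusted p = 0.264 with an estimated correlation. Of 16 nonpeptidergic nociceptor genes, 7 rose and 4 fell (camera adjusted p = 0.0673). Of 20 genes of mechanoreceptors and proprioceptors, 11 fell and 3 rose, and 12 fell when adjusted over the list alone, with camera adjusted p = 0.0115, and adjusted p = 0.315 with an estimated correlation. The potassium channel genes Kcna1 and Kcna2 fell by 1.05 and 0.79 and Necab2 rose by 1.86.

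**Figure D2:**
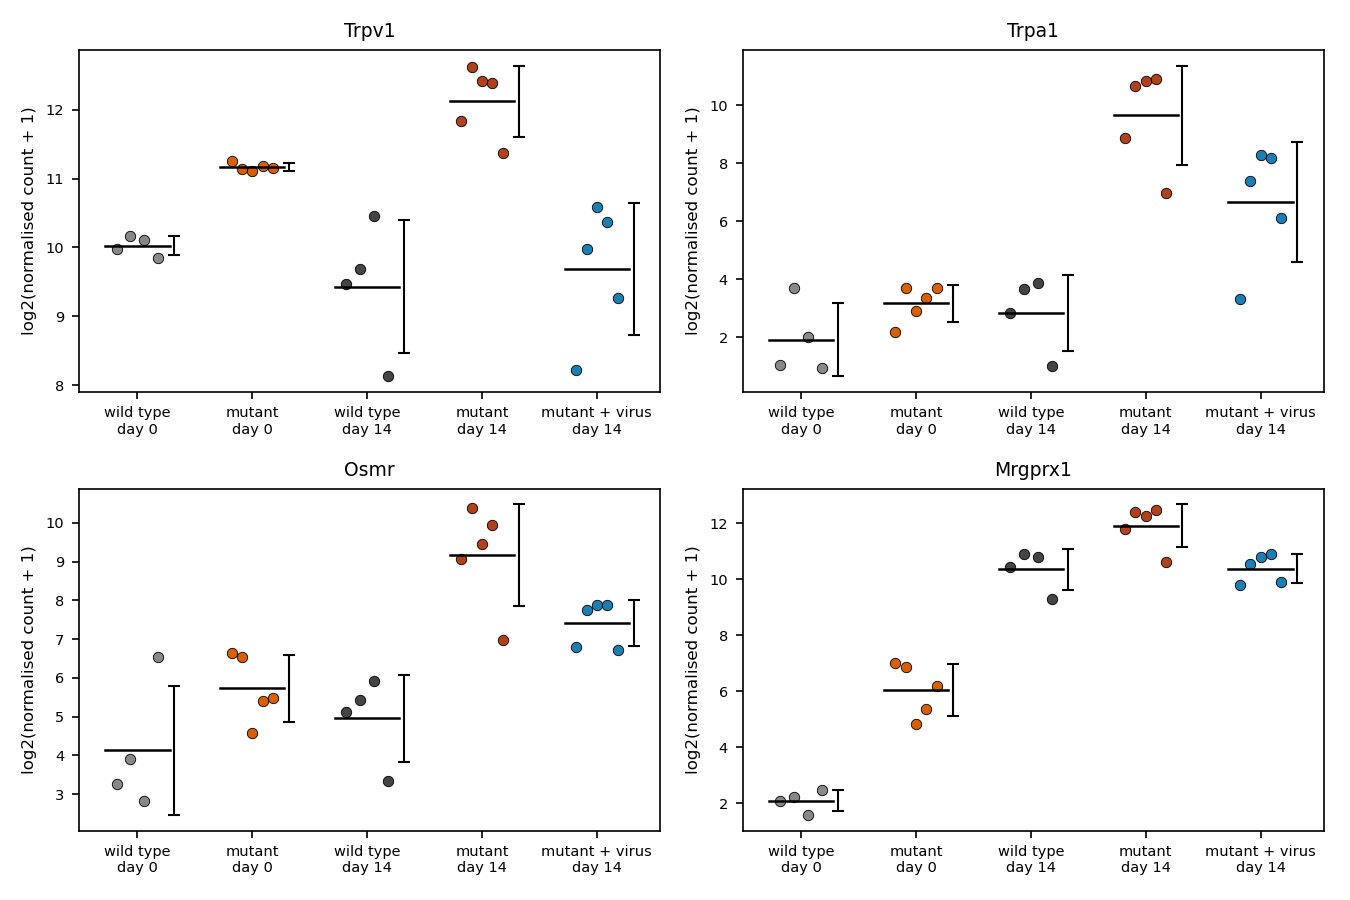
Trpv1, Trpa1, Osmr and Mrgprx1 in each sample as log2(normalised count + 1), with 1 point per sample and the mean and SD of each of the 5 groups. At day 14 the Trpv1 mean was 802 counts in wild type, 4687 in mutant and 957 in mutant with virus.

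Of 67 ribosomal protein genes, 39 rose, and 57 when adjusted over the list alone, with Rps17 at 0.70 and Rps12 at 0.73 (camera adjusted p = 5.66e-14, and adjusted p = 0.57 with an estimated correlation). Of 40 cytoskeleton genes, 21 fell, and 23 when adjusted over the list alone, with the motor gene Dync1h1 at -0.95, the spectrin gene Sptan1 at -0.78 and the neurofilament gene Nefm at -0.93 (camera adjusted p = 2.89e-07, and adjusted p = 0.315 with an estimated correlation). Long genes tended to be lower in mutant: the median log2 fold change went from 0.26 in the tenth of genes with the shortest transcripts to -0.30 in the tenth with the longest. Of 66 ion channel genes, 31 fell and 8 rose (camera adjusted p = 0.000912, and adjusted p = 0.594 with an estimated correlation), and the 4 with the smallest p all rose, Trpa1, Trpv1, the nicotinic receptor gene Chrna6 (3.11) and the potassium channel gene Kcnc4 (2.27). Adjusted over the list alone, 31 fell and 9 rose.

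Of 43 interferon genes, 16 rose and 1 fell, with the same numbers adjusted over the list alone, including the antigen presentation genes B2m (1.10) and Psmb8 (2.27) and the antiviral genes Ifih1 (2.36) and Ifit3 (2.19), with camera adjusted p = 7.41e-06, and adjusted p = 0.315 with an estimated correlation. Of 24 cholesterol synthesis genes, 14 rose, with the same number adjusted over the list alone, such as Ebp (0.62) and Msmo1 (0.67), with camera adjusted p = 6.4e-05, and adjusted p = 0.435 with an estimated correlation. Of 48 autophagy and lysosome genes, 19 fell and 2 rose, and 22 fell when adjusted over the list alone, such as the proton pump gene Atp6v0a1 (-0.58) and the protease gene Tpp1 (-0.50), with camera adjusted p = 0.00151, and adjusted p = 0.315 with an estimated correlation. Of 33 axon injury and stress genes, 14 fell and 1 rose, and 15 fell when adjusted over the list alone, including Sesn2 (-1.55) and the serine synthesis gene Psat1 (-0.98), with camera adjusted p = 0.000131, and adjusted p = 0.315 with an estimated correlation. Of 55 axon guidance genes, 16 fell and 5 rose, and 17 fell when adjusted over the list alone, including Robo1 (-1.71), Sema5a (-1.43) and, higher, Plxnc1 (2.01), with camera adjusted p = 0.0193, and adjusted p = 0.594 with an estimated correlation. This last list did not pass once the trend with transcript length was removed. Of 49 genes of oxidative phosphorylation, 4 rose and none was called adjusted over the list alone (camera adjusted p = 0.00151, and adjusted p = 0.83 with an estimated correlation). Their median of 0.19 became -0.014 with the length trend removed from each sample, and 0.032 with it removed from the fold changes. The mean log2 value of this list was 12.99 in mutant H, 12.1 to 12.4 in the other mutants and 12.1 to 12.3 in wild type.

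Of 17 sensory identity genes, 6 fell and 1 rose (camera adjusted p = 0.0566), with the transcription factor gene Isl1 at 0.63 and the neurofilament gene Nefl at -0.69. Glial genes had 3 higher and 2 lower of 26 (camera adjusted p = 0.555), and fibroblast genes 2 higher and 1 lower of 23 (camera adjusted p = 0.542). The day 14 count was 2571 with only the 9 samples compared in the fit, where the calls of Mrgprx1, Il31ra, Acacb and Nefl ended. A covariate for the style of the sample titles, which at day 14 only mutant H sets apart from the genotype, ended the calls of Mrgprx1, Mrgpra3, Il31ra, Nppb, Plcb3, Fgf21 and Nefl, and leaving out wild type 4 ended that of Mrgprx1.

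The third comparison asks what a lentivirus carrying TMEM184b changed in mutant neurons. With virus, 21 of 26 glial, 22 of 23 fibroblast and 21 of 25 p53 target genes rose and all 24 measured cholesterol synthesis genes fell. These lists passed camera at its preset correlation but not with an estimated correlation (adjusted p = 0.0647 for glia, 0.0726 for fibroblasts, 0.0647 for p53 targets and 0.0647 for cholesterol synthesis). Col1a1, a collagen of fibroblasts, went from 17.9 ± 13.2 counts to 3746 ± 1779, a log2 fold change of 8.04 ± 0.83. Plp1, a myelin protein of glia, went from 25.9 ± 9.06 to 1769 ± 443, or 6.09 ± 0.27. Hmgcs1, an early enzyme of cholesterol synthesis, fell from 32048 ± 2085 to 6759 ± 1463, or -2.27 ± 0.13. Trpv1 fell from 4687 ± 1501 to 957 ± 508, or -2.44 ± 0.37, and Trpa1 from 1199 ± 840 to 171 ± 134, or -2.99 ± 0.85.

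With virus, 8421 genes were called against mutant cultures without it, 4595 higher and 3826 lower, of which 2322 and 825 changed at least 2-fold. Under quantile normalisation the median of all genes moved from 0.04 to -0.08, and 43.0% of the genes called were higher, against 54.6%. The genes that rose most were Anxa1 (9.23), Ifitm3, the glial genes Mpz (8.39) and Pmp2 (8.21), Fst, Col1a1, Col15a1, Tnfaip2, Hspg2 and St14, with log2 fold changes of at least 7.90. Ifitm3, an antiviral gene, was listed at 0 in all day 14 mutant samples without virus and had 586 ± 306 counts with it. The genes that fell most were Syt6 (-4.51), Fgf21 (-4.50), Cdh1 (-4.42), Cyp2j12 (-4.34), Klk4 (-4.24), Gna14 (-4.19), Bcl2l14 (-4.13), Chrnb3 (-4.10), Pla2g3 (-4.10) and Pde4c (-4.08). Gna14, a G protein, went from 3527 ± 762 to 232 ± 111 counts.

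Of 26 glial genes, 21 rose and 3 fell, with the same numbers adjusted over the list alone, including Cryab (6.74) and Ttyh1 (2.59), with camera adjusted p = 8.15e-09, and adjusted p = 0.0647 with an estimated correlation. Of 23 fibroblast and mesenchyme genes, 22 rose and 1 fell, with the same numbers adjusted over the list alone, including Col5a1 (5.52), Prrx1 (6.28) and the actin gene Acta2 (7.20), with camera adjusted p = 1.83e-11, and adjusted p = 0.0726 with an estimated correlation. Of 25 p53 target genes, 21 rose and 3 fell, and 21 rose and 4 fell when adjusted over the list alone, with camera adjusted p = 4.52e-08, and adjusted p = 0.0647 with an estimated correlation. Phlda3 went from 974 ± 210 to 6971 ± 740 counts, Tnfrsf10b, a death receptor, from 143 ± 36.9 to 1967 ± 159 and Eda2r from 8.57 ± 5.09 to 1220 ± 132. All 24 cholesterol synthesis genes fell, over all genes and adjusted over the list alone, including Tm7sf2 (-2.33), Nsdhl (-2.20) and Sqle (-1.81), with camera adjusted p = 2.83e-20, and adjusted p = 0.0647 with an estimated correlation.

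**Figure D3:**
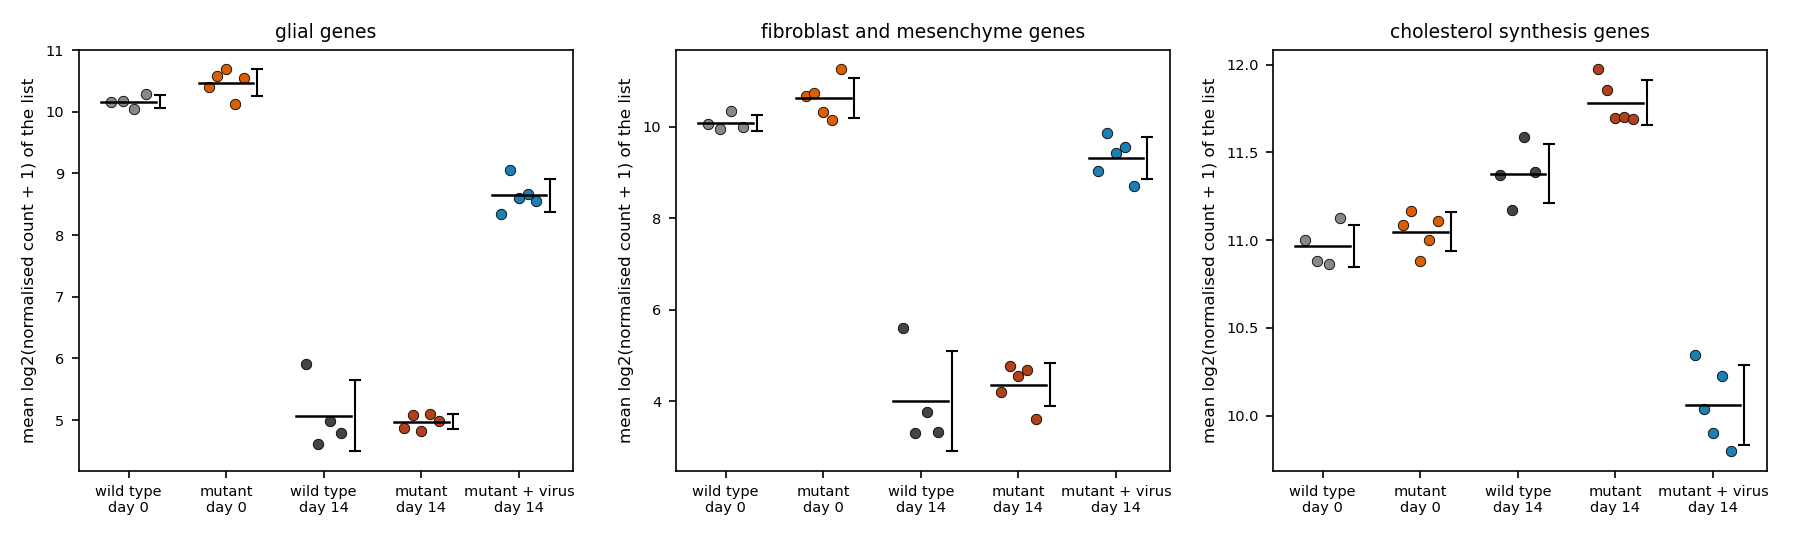
Mean log2(normalised count + 1) of the glial, fibroblast and mesenchyme, and cholesterol synthesis lists in each sample, with 1 point per sample and the mean and SD of each of the 5 groups. In the 5 animals the glial mean was 3.46 to 3.98 higher with virus than without, the fibroblast mean 4.83 to 5.10 higher, and the cholesterol synthesis mean changed by -1.89 to -1.48.

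Some genes of neurons fell too. Of 17 sensory identity genes, 12 fell and 2 rose, and 14 fell when adjusted over the list alone, with Snap25 at -0.96, the sodium channel gene Scn9a at -1.32 and, higher, the transcription factor genes Isl1 (1.04) and Prrxl1 (0.80), with camera adjusted p = 0.00515, and adjusted p = 0.413 with an estimated correlation. Of 42 synaptic vesicle genes, 22 fell and 3 rose, with the same numbers adjusted over the list alone, among them Syt11 (-1.16), Rph3a (-3.69) and, higher, the glutamate transporter gene Slc17a7 (2.29), with camera adjusted p = 0.000107, and adjusted p = 0.413 with an estimated correlation. Of 66 ion channel genes, 32 fell and 7 rose, and 36 fell when adjusted over the list alone, including P2rx4 (-1.29) and Kcna1 (-1.62), with camera adjusted p = 4.35e-05, and adjusted p = 0.443 with an estimated correlation. Of 40 cytoskeleton genes, 20 fell and 1 rose, and 22 fell when adjusted over the list alone, including the neurofilament gene Nefh (-1.34) and the tubulin gene Tubb3 (-0.84), with camera adjusted p = 5.71e-05, and adjusted p = 0.413 with an estimated correlation. Of 48 autophagy and lysosome genes, 18 fell and 7 rose, with the same numbers adjusted over the list alone (camera adjusted p = 0.0115, and adjusted p = 0.413 with an estimated correlation).

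Of 67 ribosomal protein genes, 41 rose and 1 fell, with the same numbers adjusted over the list alone (camera adjusted p = 5.99e-05, and adjusted p = 0.652 with an estimated correlation), Rpl32 among them at 1.12. Of 32 genes induced by MAP kinase signalling, 17 rose and 3 fell, with the same numbers adjusted over the list alone, including Fos (3.33), Nr4a1 (3.71) and Spry1 (4.27), with camera adjusted p = 0.00804, and adjusted p = 0.449 with an estimated correlation. Of 58 genes of Wnt signalling, 30 rose and 9 fell, with the same numbers adjusted over the list alone, including the coreceptor gene Lrp5 (5.19), with camera adjusted p = 0.00252, and adjusted p = 0.413 with an estimated correlation. Of 23 blood and macrophage genes, 12 rose and 3 fell, with the same numbers adjusted over the list alone, including Lyz2 (5.63), with camera adjusted p = 0.0231, and adjusted p = 0.443 with an estimated correlation. Of 30 proliferation genes, 17 rose and 2 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.0315, and adjusted p = 0.576 with an estimated correlation), and their median of 0.51 became -0.18 under quantile normalisation. The lists of sensory identity, synaptic vesicle, cytoskeleton, autophagy, Wnt signalling, blood and proliferation genes did not pass under quantile normalisation, where 8 lists did.

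Of 20 itch neuron genes, 7 fell and 3 rose with virus, with the same numbers adjusted over the list alone (camera adjusted p = 0.239). Beside Trpv1 and Trpa1, Cysltr2 (-3.51), Mrgpra3 (-2.50), Osmr (-1.75), Mrgprx1 (-1.53) and Plcb3 (-0.89) fell, and Npr3 (6.18), Il13ra1 (2.30) and Crlf2 (0.52) rose. The mean change of the list was -1.20 in animal B, -0.77 in C, -0.44 in E, -0.41 in FG and 0.62 in H. The call of Osmr ended without any of 5 samples and that of Crlf2 without any of 3, and the style of titles as a covariate ended those of Trpa1, Cysltr2, Mrgpra3, Osmr, Mrgprx1 and Crlf2.

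Of the 4224 genes called between mutant and wild type at day 14, 1189 (28.1%) were called in the opposite direction with virus. With only the groups compared in the fit, this count was 678. Among them, 538 were higher in mutant and fell with virus, where independent lists would share 479, and 651 were lower in mutant and rose, where independent lists would share 638. Another 1235 genes moved further from wild type, where independent lists would share 1107. The fold changes of both contrasts had a correlation across genes of -0.0636 and a covariance of -0.0521. In 50 simulations of unchanged groups, which share the unrescued mutants, the mean correlation was -0.470 and the mean covariance -0.0357. When the unrescued mutants were split between the contrasts in 20 ways, 318 to 964 genes moved back, a median of 0.976 times the number expected of independent lists.

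The fourth comparison asks what still differed from wild type in mutant neurons with virus. Trpv1 had 957 ± 508 counts with virus and 802 ± 463 in wild type, a log2 fold change of 0.25 (limma adjusted p = 0.599), and Mrgprx1 differed by 0.02 (limma adjusted p = 0.971). The absence of these calls does not show a return to the wild-type level in neurons. The mean log2 value of sensory identity genes was 13.5 with virus and 14.1 in wild type, and a dilution of neuronal RNA was not removed. Trpa1, at 3.82, Osmr, at 2.46, and Jak1, at 1.94, were still higher than in wild type. Sparc, a matrix protein, was at 13562 ± 4023 counts with virus and 90.9 in wild type, and Trpm8, the cold channel, fell from 5045 ± 1526 in wild type to 192 ± 155.

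In this comparison 9564 genes were called, 5147 higher and 4417 lower, of which 2701 and 1151 changed at least 2-fold. Under quantile normalisation the median of all genes moved from 0.05 to -0.10, and 43.6% of the genes called were higher, against 53.8%. The genes that rose most were Anxa1 (9.80), Igfbp7, Acta2, Fst, Eda2r, Bgn, Lox, Prss23, Sparc and Col1a1 (8.58), and those that fell most were Fgf21 (-8.28), Fev, Eno1b, Adm2, Fut1, Cdsn, Cass4, Hapln4, Trpm8 (-4.92) and Stc2 (-4.81). Of 20 itch neuron genes, 12 rose and none fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.00708, and adjusted p = 0.452 with an estimated correlation). Of 67 ribosomal protein genes, 64 rose, and 65 when adjusted over the list alone (camera adjusted p = 2.83e-12, and adjusted p = 0.452 with an estimated correlation). Of 43 interferon genes, 27 rose and 4 fell, with the same numbers adjusted over the list alone, and B2m went from 1330 ± 143 to 8057 ± 1094 counts (camera adjusted p = 0.000471, and adjusted p = 0.452 with an estimated correlation). Of 24 cholesterol synthesis genes, 23 fell, with the same number adjusted over the list alone (camera adjusted p = 1.41e-12, and adjusted p = 0.165 with an estimated correlation). Of 40 cytoskeleton genes, 33 fell, with the same number adjusted over the list alone (camera adjusted p = 1.89e-09, and adjusted p = 0.179 with an estimated correlation).

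**Figure D4:**
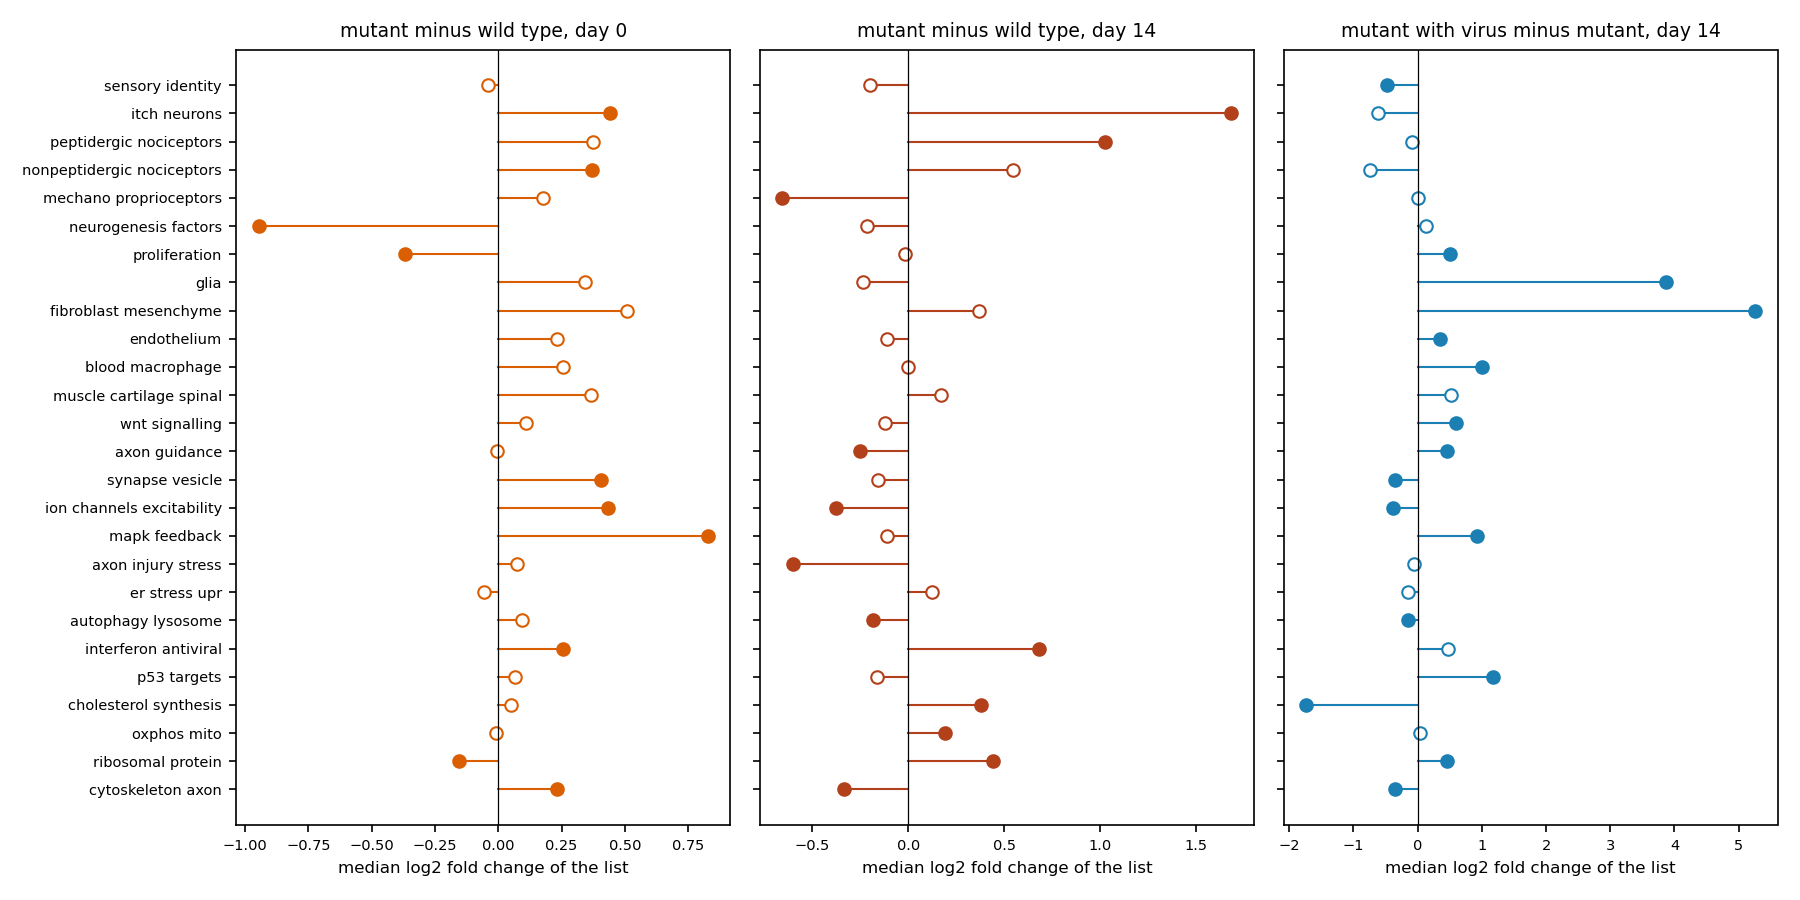
Median log2 fold change of each of the 26 gene lists in mutant against wild type at day 0, in mutant against wild type at day 14 and in mutant with virus against mutant without. Filled points mark a camera adjusted p under 0.05 at the preset correlation. With an estimated correlation, only the neurogenesis list passed at day 0, and no list passed at day 14 or with virus against no virus. The medians reach -0.95 for neurogenesis genes at day 0, 1.68 for itch neuron genes at day 14 and 5.26 for fibroblast and mesenchyme genes with virus.

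Most genes changed between day 0 and day 14 of culture in both genotypes, but the day 0 samples held other cells too. In wild type, the mean log2 value of blood genes fell from 8.77 to 1.85, of fibroblast genes from 10.1 to 4.01 and of glial genes from 10.2 to 5.07. Changes within neurons were not separated from a loss of other cells. In wild-type samples, Calca, the gene of the pain peptide CGRP, rose from 55.0 ± 17.1 to 51307 ± 15524 counts, or 9.84 ± 0.30, and Trpm8 rose by 11.97. The globin gene Hbb-bs fell by 13.62 and the imprinted growth gene Igf2 by 11.26. Of 12588 genes called in wild type, 5671 rose and 6917 fell, and of 12829 in mutant, 5844 rose and 6985 fell. Of these, 4854 rose in both genotypes, where independent lists would share 2072, and 5999 fell in both, where independent lists would share 3021. Under quantile normalisation the median of all genes moved from -0.15 to 0.12 in wild type and from -0.12 to 0.18 in mutant, and the share of called genes that were higher became 53.9%, against 45.1%, in wild type and 56.4%, against 45.6%, in mutant.

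In wild-type culture, 35 of 42 synaptic vesicle genes rose (camera adjusted p = 1.8e-08, and adjusted p = 0.124 with an estimated correlation), as did 49 of 66 ion channel genes (camera adjusted p = 2.22e-08, and adjusted p = 0.254 with an estimated correlation), and 44 of 49 genes of oxidative phosphorylation (camera adjusted p = 7.07e-07, and adjusted p = 0.533 with an estimated correlation). Syngr1 rose by 3.39, Vamp1 by 4.25 and the sodium channel gene Scn1b by 5.98. Of 28 neurogenesis genes, 26 fell (camera adjusted p = 2.22e-08, and adjusted p = 0.0429 with an estimated correlation). Genes of dividing and of other cells fell too: 27 of 30 proliferation genes (camera adjusted p = 1.8e-08, and adjusted p = 0.0709 with an estimated correlation), 22 of 26 glial genes (camera adjusted p = 5.32e-06, and adjusted p = 0.0946 with an estimated correlation) and 22 of 23 fibroblast genes (camera adjusted p = 5.68e-06, and adjusted p = 0.223 with an estimated correlation). Of 67 ribosomal protein genes, 65 fell (camera adjusted p = 2.18e-07, and adjusted p = 0.538 with an estimated correlation). These counts were the same adjusted over the list alone, except 45 for oxidative phosphorylation.

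In mutant culture, Fosb fell from 42712 ± 8750 to 2.62 counts, and Tmem233 (12.16), Chrna6 (10.15) and Calca (10.00) were among the genes that rose most. Of 28 neurogenesis genes, 25 fell, as did 22 of 23 blood, 14 of 15 endothelial and 49 of 58 Wnt signalling genes, and these 4 lists passed camera with an estimated correlation too (adjusted p = 0.0402 for each). Of 67 ribosomal protein genes, 40 fell and 1 rose, and 39 fell when adjusted over the list alone (camera adjusted p = 0.0206, and adjusted p = 0.736 with an estimated correlation).

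The last comparison asks whether the change from day 0 to day 14 differed between mutant and wild type. It called 3768 genes, 1599 with a higher change in mutant and 2169 with a lower one, and 6537 with sample weights. Of these, 784 differed between genotypes at day 0 only, 2145 at day 14 only and 272 at both days in opposite directions. The largest positive differences were in Cyp2j12 (5.83), Trpa1 (5.55), Neurog1 (5.49), A3galt2, Pax8, Cysltr2, Pde9a, Gfra2, Pde4c and Gfra3 (4.58), and among the largest negative ones were Fgf21 (-4.74), Ptgs2 (-4.04), Fosb (-3.77), Grin2b (-3.61), Cd276 (-3.56) and Nfatc2 (-3.54).

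Of 66 ion channel genes, 35 had a lower change in mutant and 4 a higher one, or 43 and 7 adjusted over the list alone (camera adjusted p = 3.85e-09, and adjusted p = 0.339 with an estimated correlation). Of 67 ribosomal protein genes, 32 had a higher change, or 63 adjusted over the list alone (camera adjusted p = 1.63e-15, and adjusted p = 0.379 with an estimated correlation). Of 40 cytoskeleton genes, 23 had a lower change, or 26 adjusted over the list alone (camera adjusted p = 4.83e-09, and adjusted p = 0.339 with an estimated correlation). Of 20 itch neuron genes, 9 had a higher change and 1 a lower one, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.000842, and adjusted p = 0.349 with an estimated correlation). Of 28 neurogenesis genes, 11 had a higher change and none a lower one, or 12 and 2 adjusted over the list alone (camera adjusted p = 9.67e-05, and adjusted p = 0.339 with an estimated correlation). The mean log2 value of this list was 10.2 in wild type and 9.30 in mutant at day 0, and 5.70 and 5.64 at day 14. Fosb had 7809 to 17561 counts in wild type and 31203 to 52945 in mutant at day 0, and at most 18.3 and 3.55 at day 14. The differences of this list and of Fosb thus lay at day 0, where the genotype was not tested apart from stage. Quantile normalisation gave a higher change in 53.9% of the genes called, against 42.4%. Without the 3 day 0 mutants that stand apart, 799 genes were called, and the calls of Fgf21, Ptgs2, Pax8 and Nfatc2 ended.

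Across both days, 150 genes were higher and 91 lower in mutant at each, where independent lists would share 144 and 101. Another 205 were higher at day 0 and lower at day 14, where independent lists would share 159, and 67 were lower and then higher, where independent lists would share 90.7. The samples of both days come from the same animals, which the numbers for independent lists do not take into account.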

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

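The test on the globin switch, the list and test of spinal cord genes, the fits with the length trend removed and the splits of the animals were chosen only after the results they bear on had been seen.

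The change in culture differed between the genotypes by a test of the difference itself, which called 3768 genes. No other split of the samples, of 100 run and the real one included, gave as many, so 1 of 100 did, and the highest of the others gave 2867. For mutant against wild type at day 0, 2 of 100 splits gave 1870 genes or more, so chance can be excluded at 0.05, but the highest other split gave 3172 genes. That split groups mutant H with the 4 wild types, which points to a structure among the mutants. For mutant against wild type at day 14, 1 of 100 splits gave the real 4224 or more, and the highest other, with mutant B among the wild types, gave 4178. Chance can also be excluded for virus against wild type (1 of 100, real 9564, highest other 8237). The other comparisons share animals, so the real split was set beside those that part all pairs of samples, which are too few for a share under 0.05: 16 for virus against no virus (1 as large, real 8421, highest other 3913), 8 for wild-type culture (1 as large, real 12588, highest other 5) and 16 for mutant culture (1 as large, real 12829, highest other 8752). Splits that keep some pairs together gave up to 4054, 18 and 8893 genes.

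Each of the 5 groups of samples was screened on 28 measures, and in 8 of these 140 screens 1 sample lay far from the others, where chance gives about 1 in 20. All values are the mean log2 of a list. At day 0, wild type 4 had 10.7 for synaptic vesicle genes (others 10.9) and 8.61 for ion channel genes (others 8.97 to 9.04). Mutant C at day 0 had 7.21 for muscle, cartilage and spinal genes (others 4.58 to 5.31), and mutant H had 10.2 for genes induced by MAP kinase signalling (others 10.9 to 11.1). At day 14, mutant H had 7.63 for genes of mechanoreceptors and proprioceptors (others 7.96 to 8.05) and 12.99 for genes of oxidative phosphorylation (others 12.1 to 12.4). With virus, animal B had 8.88 for peptidergic nociceptor genes (others 9.53 to 9.75) and animal H had 10.6 for genes of the unfolded protein response (others 10.8).

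At day 0, 13 of 32 genes induced by MAP kinase signalling, 17 of 42 synaptic and 20 of 66 ion channel genes were called higher in mutant, in lists that did not pass with an estimated correlation (adjusted p = 0.165, 0.165 and 0.362), and 14 of 28 neurogenesis genes lower (adjusted p = 0.00937). Harsher handling of the mutant cells cannot be told apart, since heat shock genes had a median log2 fold change of 0.0305 with an SD of 0.68 over members that went both ways. Of 12 measured, 2 were called lower in mutant, Hspa1a (-1.28 ± 0.24) and Hspa1b (-1.70 ± 0.25), and 1 higher, Dnajb1 (0.53 ± 0.095). Spinal cord tissue in the wild-type dissections cannot be told apart either as a cause of the whole pattern. The spinal cord list had a median of -1.98 with the genes that prompted it. It was -0.86 over the 15 genes left without those named before and 5 that another list holds, with 14 lower and 1 higher. In the whole list, Pax3 at 269 against 59.5 counts and Zic1 at 1904 against 1194 were among the most abundant. Wild type 1, a single sample, had a spinal cord mean of 3.42, below those of the mutants, with a neurogenesis mean of 10.3. For mutant embryos of a later stage, both predictions were met, the one on globin chosen after its values were seen. The other was set within genotypes, so it cannot show a difference in stage between them. It also left out the genes induced by MAP kinase signalling. Their mean was 10.7 in wild type 4, a single sample, against 9.51 to 9.75 in wild types 1 to 3, while its ion channel mean was the lowest, at 8.61. Within the genotypes, neurogenesis and ion channel values went in opposite directions over the 9 samples (Pearson r = -0.877, exact p = 0.000347; Spearman rho = -0.933, exact p = 0.0059; r = -0.809 without the 2 samples farthest from the median). The log2 ratio of adult to embryonic globin was higher in mutants by 1.72, at 1.06 to 1.93 against -0.516 to 0.143 in wild type (exact permutation p = 0.00794). The globin values go with a later stage of the mutants, but do not separate it from the genotype. An effect of the genotype was not tested apart from stage, handling and dissection.

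At day 14, 39 of 67 ribosomal protein genes were called higher in mutant, 21 of 40 cytoskeleton genes lower, and 31 of 66 ion channel genes lower and 8 higher, in lists that did not pass with an estimated correlation (adjusted p = 0.57, 0.315 and 0.594). A trend of fold change with transcript length is argued against as the whole cause for the ribosomal protein genes, whose median was 0.271 with the trend removed, against 0.44 before; their mean per sample then differed by 0.27 (exact p = 0.0397). The authors' scaling is argued against too, since the median stood 0.499 above that of all genes after quantile normalisation (exact p = 0.0159 for the mean per sample). The cytoskeleton genes had a mean difference of -0.30 with the length trend removed (exact p = 0.0238), while for ion channel genes the mean difference was -0.12 before (exact p = 0.333) and 0.02 after, and their median was -0.38 before and -0.23 after, so the part of the trend in that list stays open. An effect of the genotype stays open as a hypothesis for the ribosomal protein and cytoskeleton genes. It was not tested apart from the stage of the embryos, which gave the samples of both days.

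In cultures with virus, 21 of 26 glial and 22 of 23 fibroblast genes rose, in lists that did not pass with an estimated correlation (adjusted p = 0.0647 and 0.0726), and 1189 genotype genes moved towards wild type. Cells of other types in these cultures may account for the first part. The 2043 genes that fell by at least 3 on the log2 scale in wild-type culture, in samples outside this comparison, had a median change with virus of 1.57. Of them, 64.4% were higher with virus, against 23.5% of other genes. This set may hold glial and fibroblast genes, so it is not independent of their rise. Among the genes that rose most, some were above their mean in day 0 mutants, such as Anxa1 (3302 against 148 counts) and Pmp2 (365 against 1.14). Others were below it, such as Mpz (564 against 5497). Whether cells of other types merely remained from day 0 cannot be told apart. Why such cells would be more abundant was not tested, and the virus, its addition to the culture and the restored gene are confounded. For the second part, 1117 genes would move back by independent lists, and whether the unrescued mutants shared by both comparisons add to the count cannot be told apart, since it was 1.06 times that number with no split, 0.976 times with these mutants split and 1.05 times with the animals split. Whether genes higher in mutant fell with virus beyond a dilution of neuronal RNA cannot be told apart, because their change differed from that of matched lists by a median of -0.0274, with 10 of 20 splits below the range of matched lists and 8 above.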

How the results depend on the processing

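The fits with a length or GC trend removed, without genes lost in wild-type culture, without the 3 day 0 mutants that stand apart, without animal H and with the animals split were chosen after seeing the data. Across the alternatives, 30634 of the gene values kept their direction and side of the threshold, 749 became weaker, 365 stronger and 5 reversed, and of the list values 784 were kept, 22 became weaker, 21 stronger and 5 reversed. Where a count moved, the cause was not tested unless fewer samples in the fit give it.

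The day 0 count of 1870 became 2837 (46.7% of them higher, against 61.3%) under quantile normalisation, 6328 with sample weights and 60 without the 3 mutants that stand apart, which leaves 2 mutants; other pairs of 2 mutants gave 144 to 2350. Leaving out each sample gave 924 to 3034. The day 14 count of 4224 became 2571 with only the samples compared, and 3321 to 4769 with each sample left out. The interaction count of 3768 became 6537 with sample weights and 799 without the 3 mutants. The count of 1189 genes moved back became 678 with only the samples compared, and in 1 split of the unrescued mutants 318 and in 1 split of the animals 279, with fewer samples in each contrast; leaving out samples gave 931 to 1336. With an estimated correlation, 1 list passed at day 0, 0 at day 14, 0 for virus against no virus, 0 for virus against wild type, 1 in wild-type culture, 4 in mutant culture and 0 for the interaction. For virus against no virus 8 lists passed under quantile normalisation, and for virus against wild type 23 passed fry, which does not compare a list with other genes.

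These values reversed, and the cause was not tested. Under quantile normalisation, Col2a1 became -0.13, Ankrd54 -0.00240 and Dmc1 -1.06 with virus against no virus, and Lpar5 became 0.89 in mutant culture. The proliferation list became -0.18 against no virus and -0.24 against wild type, and that of oxidative phosphorylation 0.21 against no virus. With the length trend removed from each sample, Cby1 became -0.22 with virus against wild type, and oxidative phosphorylation -0.014 at day 14 and -0.062 in the interaction. The day 14 value of oxidative phosphorylation was 0.032 with the trend removed from the fold changes instead, so its sign depends on the method.

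With the animal as a block, the interaction called 2786 genes by the letters in the titles, 4225 with the unlettered mutant as E and 4397 with a random effect, whose within-animal correlation was 0.123. With the letters as a block, Tmem184b became a call in wild-type culture (0.41, adjusted p = 0.00179) and in the interaction (adjusted p = 0.0404), and the block changed no call of a gene or list given in the comparisons. In the check on simulated data, 48% of 1.5-fold changes were recovered at day 0, 60% at day 14 and 64% for virus against no virus, so smaller changes were often missed.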

Other observations

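The tests on Xist and on the globin switch were chosen only after the result was seen, and the test on genes near Tmem184b was not.

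Members of some lists that did not pass changed all the same. Genes of the unfolded protein response went apart at day 14: of 21, 6 rose and 6 fell in mutant (camera adjusted p = 0.542), with the chaperone gene Pdia6 at 0.85 and Manf at 0.65 higher and Edem1 at -0.68 lower. Of 42 synaptic vesicle genes at day 14, 5 rose and 12 fell (camera adjusted p = 0.157), where the adhesion gene Nrxn3 rose by 1.87 and the calcium sensor gene Syt2 fell from 11454 ± 1417 to 4243 ± 1929 counts. Of 58 Wnt signalling genes at day 14, 1 rose and 12 fell (camera adjusted p = 0.157), including Fzd10 (-2.91) and Fzd1 (-0.94). Of 25 p53 target genes at day 14, 2 rose and 7 fell (camera adjusted p = 0.0504), including Sesn2 and the cell cycle inhibitor gene Cdkn1a, which went from 18403 ± 4808 to 11333 ± 1474 counts.

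With virus, some genes of the interferon response and of neuron types changed while their lists did not pass. Of 43 interferon genes, 16 rose and 8 fell against mutant cultures without virus (camera adjusted p = 0.185), with the peptide transporter gene Tap1 at 4.12 higher, and the median of 0.48 became -0.30 under quantile normalisation. Of 16 nonpeptidergic nociceptor genes, 3 rose and 8 fell (camera adjusted p = 0.1), including the ATP receptor gene P2rx3, which went from 28767 ± 6030 to 12416 ± 3414 counts, and Grik1, which rose by 2.07. Of 17 peptidergic nociceptor genes, 1 rose and 6 fell (camera adjusted p = 0.147), including Trpm8 (-2.70) and the growth factor receptor gene Kit (-1.92).

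A hypothesis was that DNA of the embryonic stem cells in which the trap was made, around Tmem184b, changes genes near it. Of 209 genes within 5 Mb, 2 were called at both days, or 0.957%, against 3.27% of other genes, a ratio of 0.293 (one-sided exact Fisher p = 0.992). This argues against such DNA as a cause of widespread changes near Tmem184b at both days. The shares count calls in opposite directions too, and they cannot exclude an effect on single genes. The genes were Mief1 and Plec, named after their values were seen, and only Mief1, at -0.25 and -0.29, went the same way at both days. Calls at a single day were not tested against it. Of the 29 neighbours in the list fixed before, 2 rose and 4 fell at day 0, Maff (2.08), Syngr1 (0.46), Ankrd54 (-0.36), Gtpbp1 (-0.40), Sun2 (-0.37) and Tab1 (-0.40), and 4 others rose at day 14, Polr2f (0.44), Tomm22 (0.34), Cbx7 (0.54) and Rpl3 (0.38). Of these day 0 calls, only that of Syngr1 held without the 3 day 0 mutants that stand apart.

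Eno1b and H2-T24 followed the numbers of the wild-type samples. Eno1b had 77.7 counts in wild type 2 at day 0 and 88.8 at day 14, and at least 4761 in each of the other wild-type samples at both days. H2-T24 had 15.8 counts in wild type 4 at day 0 and 5.08 at day 14, and at least 86.2 in each of the other wild-type samples. Both had low counts in all mutants, up to 63.9 for Eno1b and 43.8 for H2-T24.

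Y-linked transcripts were at high levels in 2 samples of each group: wild types 3 and 4 at both days, mutants C and the unlettered one at day 0, and C and E at day 14 with and without virus. Among these samples, Xist was at 4.47% to 6.97% of the mean of the other mutants at day 0, 6.26% to 8.06% at day 14 and 5.40% to 8.54% with virus, and in wild type at no more than 0.0824%. Whether female cells were mixed into the male mutant samples cannot be told apart, since the lowest value, 4.47%, is among those that raised the question and no other value tests it.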
